A study of Mus musculus with 2 samples.

How the data were processed

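The deposited data were single-cell 3' RNA sequencing libraries of splenic NK cells isolated by flow cytometry, 1 from control mice and 1 from mice under dietary restriction (DR). Per the labels' protocols, cells were loaded on a 10x Genomics Chromium controller with the Next GEM Single Cell 3' chemistry. The deposited values were whole-number UMI counts per gene and cell barcode, not normalized, as written by Cell Ranger per the file headers. The matrix headers name Cell Ranger version 5.0.1, whereas the submitters' processing notes name version 2.1.1 and the genome build mm10; the conflict could not be settled from the files. The files list 32285 genes, 78 of which share a symbol with another and were kept apart by identifier. No barcode held fewer than 501 UMIs, so barcodes without cells were not available and free RNA in the droplets could not be estimated or subtracted; B-like cells served as the reference for it. The labels do not mention removal of doublets.

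Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, which removed 215 control and 167 DR barcodes. Doublets were scored per library with the Scrublet algorithm, using 2 simulated doublets per cell and an expected rate of 0.05. Its automatic threshold marked 0 of 5487 control cells and 1 of 6120 DR cells and was judged not to have worked. The top-scoring cells were therefore called down to the score reached at the share that the cell load predicts, 0.8% per 1000 scored cells. All cells tied at that score were called, so the calls exceeded that share. This rule was chosen after the data were seen. It removed 279 control cells (5.08%) and 309 DR cells (5.05%), with medians of 12977 and 11665 UMIs against 7139 and 5738 in the other cells. This left 5208 control and 5811 DR cells.

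Counts per cell were scaled to 10000 and log-transformed for clustering only. Both libraries were clustered together with no batch integration, on 2000 variable genes picked per library, 30 principal components, 15 neighbours and Leiden resolution 0.6. The 18 clusters were named from marker lists fixed before the data were examined. A marker counted at 20 CPM or more and at least 25% of the highest cluster's level, and a name needed at least 3 markers and 50% of its list. These limits, unlike the lists, were set after the files were opened. Clusters that passed for several types of the same lineage, such as NK and ILC1, took the name with the largest share of markers. Clusters passing for more than 1 lineage, with a median depth under 1/3 of the library's and no marker of the class among the top 10 genes, or led by more markers of another class than of their own among the top 10 genes by fold over cells outside the class, stayed unnamed. NK-like cells were then clustered again with the same settings into 9 clusters, and a cluster was called immature-like or mature-like when at least 60% of that stage's markers and under 33% of the other stage's lay above the level of all NK-like cells. A cluster was called proliferating when at least 60% of the cell cycle genes were over 2-fold above that level. The remaining 4 NK-like clusters, led by Tnfrsf9 and Spp1, by Igkc and Cd74 at low RNA content, by Ccl4 and Nr4a1, and by Cxcl10 and Ifit1, held 11.2% of control and 6.24% of DR NK-like cells and stayed unnamed. A cluster of immature-like cells was led by Batf3 and the T cell receptor complex gene Cd3d.

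For each class the raw counts of its cells were summed per library and expressed as CPM of all UMIs of those cells (36203507 in control and 27548462 in DR NK-like cells). CPM have exact Poisson intervals, ratios exact conditional binomial intervals, and shares of cells exact Clopper-Pearson intervals, all at 95%. Cells are not replicates, and with 1 library per group no test was possible and no p-value is given. Genes with a mean of at least 20 CPM were described. A gene was called higher or lower by size only, at a ratio of at least 1.25 either way (25% higher or 20% lower) with an interval that leaves out a ratio of 1. The median log2 ratio of all described genes was -0.064, and it was 0 under median-of-ratios scaling by construction. Each list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and its counting interval came from 1000 Poisson redraws.

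Named genes were the 12 with the largest ratio each way, ranked by the end of the interval nearest 1, without mitochondrial, ribosomal, immunoglobulin, haemoglobin and T cell receptor genes, markers of other cell types and unnamed gene models. Up to 4 members of each of 25 lists with the largest absolute log2 ratio were added, together with Eomes, Tbx21, Tcf7, Cd27, Itgam, Klrg1, Ifng, Gzma, Gzmb, Prf1 and Mki67. Some genes are named by several parts of this rule. The rule and the lists were fixed before the data were examined; Rbm3 and the heat shock chaperones were added after Cirbp had been seen. The 25 lists covered immature, mature and cycling NK cells, transcription factors, effectors, cytokines, activating and inhibitory receptors, homing, signalling and stress responses, energy metabolism, biosynthesis, apoptosis and antigen presentation, with the mitochondrial and ribosomal genes. Of 13 cell type lists, the NK list had a median log2 ratio of -0.071 in NK-like cells (percentile 22.0) and the T cell list had 4 genes measured; the other 11 had fewer than 3 genes measured and were given no median. For shares of cells with a UMI, each cell was thinned without replacement to 3800 UMIs, the 10th percentile of NK-like cells rounded down, or to 4900 as an alternative.

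Alternatives planned in advance were a stricter filter (1000 genes, 5% mitochondrial UMIs), no filter, doublets kept, single-cell gating in place of clusters (a UMI of Ncr1 or Klrb1c and none of 6 T, B and myeloid genes), resolution 1.2, centring each library, other thinning depths, 3 other scalings, other expression limits, a ratio of 1.5 and clusters weighted equally. Added after the data were seen were the removal of NK-like cells with over 1% of UMIs from 59 marker genes of other lineages, of the proliferating cluster, or of low-RNA clusters, and equal weighting of clusters of at least 50 cells per library or of clusters made after centring, the mature NK list inside each mature-like cluster, and its shares of thinned cells with a UMI. The calling step was tested on simulated counts for 5897 genes, 200 of them changed. The counts were Poisson draws from a profile pooled over all barcodes of both libraries, at the depth of all barcodes rather than of NK-like cells. They held no spread between cells, animals or libraries, so the rates that follow cover counting error only. The intervals held the true ratio for 95.5% of genes, no unchanged gene was called, and 0%, 62%, 100% and 100% of genes changed by 1.1-, 1.25-, 1.5- and 2-fold were called. Of 200 random lists 4% fell outside the central 95%.

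Coordinates came from the GENCODE vM21 annotation of the same assembly, 1-based, matched on the Ensembl identifier for all 113 genes looked up; the release may differ from the one the authors used. Software was Python 3.11.15, scanpy 1.11.5, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.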

Results

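Splenic natural killer (NK) cells, sorted by flow cytometry from control mice and from mice under dietary restriction (DR), were profiled by droplet-based single-cell RNA sequencing of transcript 3' ends. Each group was represented by 1 library, so no difference between the groups had a replicate check. The labels gave neither the number of mice, nor whether they were pooled, nor the sorting gate. The control library held 5702 cell barcodes and 44526828 unique molecular identifiers (UMIs), with a median of 7152 UMIs and 2565 genes per barcode. The DR library held 6287 barcodes and 42134212 UMIs, with a median of 5782 UMIs and 2161 genes. Mitochondrially encoded transcripts made up a median of 1.63% of UMIs in the control library and 2.57% in the DR library. After filtering, 5208 control cells and 5811 DR cells were kept. A gene counted as higher in the DR library by size only, at a level at least 25% above control, and as lower at a level at least 20% below control, with an interval that left out a ratio of 1. Intervals given below are 95% intervals that cover counting error only, and all comparisons are between these libraries rather than between the conditions in general.

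The first comparison asked which cells the sorted samples contained. NK-like cells, named from transcripts such as Ncr1 (an activating receptor of NK cells), Klrb1c (NK1.1) and Prf1 (perforin), made up 89.1% of control cells (4640 cells, exact Clopper-Pearson interval 88.2 to 89.9) and 77.2% of DR cells (4485 cells, 76.1 to 78.3). B-like cells, named from Cd79a, Ms4a1 and immunoglobulin transcripts, made up 2.96% of control cells (154 cells, 2.51 to 3.45) and 8.26% of DR cells (480 cells, 7.56 to 9.0). T-like cells carrying Cd3e, Cd8b1 and Trac transcripts formed a single cluster with 4 control cells (0.0768%, 0.0209 to 0.197) and 301 DR cells (5.18%, 4.62 to 5.78). ILC1-like cells, named from Il7r (the interleukin-7 receptor), Tmem176a and Cxcr6, made up 6.13% of control cells (319 cells, 5.49 to 6.81) and 7.18% of DR cells (417 cells, 6.53 to 7.87). A further 1.75% of control cells (91 cells) and 2.20% of DR cells (128 cells) lay in 4 clusters that kept no name, among them a cluster led by Lyz2, S100a9 and S100a8, transcripts of myeloid cells, with 1 control cell and 28 DR cells. These shares were set in part by the sorting gate and its purity, and the DR library had fewer UMIs per cell.

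Eomes, the T-box transcription factor named in the series title and required for NK cell maturation, was at nearly the same level in NK-like cells of both libraries. Its level was 330.4 counts per 1000000 UMIs (CPM) in control NK-like cells (325 to 336, from 11962 UMIs) and 325 CPM in DR NK-like cells (318 to 331, from 8944 UMIs), a log2 ratio of DR over control of -0.025 (-0.065 to 0.014). With this scaling the counting interval lay well inside the limits of 25% higher and 20% lower. Tbx21, which encodes the related factor T-bet, was at 149 CPM in control cells and 142 CPM in DR cells (log2 ratio -0.074, -0.13 to -0.014). The Eomes gene (ENSMUSG00000032446) lies on chromosome 9 between positions 118478212 and 118486132 on the plus strand of the mm10 assembly. Tbx21 (ENSMUSG00000001444) lies on chromosome 11 between 97098071 and 97115331 on the minus strand. The Eomes log2 ratio turned slightly positive, to 0.039, with median-of-ratios scaling, and it was -0.24 when the 9 NK-like clusters were weighted equally. Inside each of these 9 clusters the ratio was below 0, with no intervals given. It ranged from -0.012 in a mature-like cluster (377 control and 2075 DR cells) to -1.08 in the cluster of proliferating cells (96 control and 33 DR cells). The ratio over all NK-like cells may therefore also reflect a different mix of clusters. Averaged over the 7 clusters of at least 50 cells per library, the Eomes ratio was -0.089. Igkc was among the top genes of the proliferating cluster, so RNA of other lineages may enter its ratio and the -0.24, to which this cluster contributed.

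Transcripts of mature NK cells were lower in the DR library and transcripts of immature NK cells were higher. Cx3cr1, the fractalkine receptor of terminally mature NK cells, had the largest difference of the ranked genes, at 124 CPM (121 to 128) in control and 20.4 CPM (18.7 to 22.1) in DR NK-like cells, a level 6.10-fold higher in control (log2 ratio -2.61, -2.74 to -2.48). Klrg1, an inhibitory receptor acquired late in maturation, was at 219.7 CPM (215 to 225) in control and 103 CPM (99.2 to 107) in DR cells (log2 ratio -1.09, -1.16 to -1.03). Of the 11 measured genes of the mature NK list, 9 were at least 20% lower in the DR library, 2 were between the limits and none was higher, with a median log2 ratio of -0.44. Zeb2, a transcription factor of terminal NK maturation, had a log2 ratio of -0.59, S1pr5, a sphingosine-1-phosphate receptor used in NK cell egress, -0.56, Itgam (CD11b) -0.45 and Gzmb (granzyme B) -0.44. Of the 10 measured genes of the immature NK list, 6 were at least 25% higher, 1 was lower and 3 were between the limits, with a median log2 ratio of 0.60. Ctla2a, which encodes a cathepsin inhibitor, was at 407 CPM in control and 791 CPM in DR cells (log2 ratio 0.96, 0.93 to 0.99). Il7r had a log2 ratio of 0.88, Emb (embigin, an adhesion protein) 0.83, Ltb (lymphotoxin beta) 0.64 and Cd27, a receptor of the tumour necrosis factor receptor family, 0.58, whereas Kit, the stem cell factor receptor, was at -0.76. The medians of the mature and immature lists lay at percentiles 0 and 100 among 10000 random lists of the same size matched on mean expression. Weighting the 9 NK-like clusters equally brought the medians to -0.28 and 0.33, and weighting the 7 clusters of at least 50 cells per library equally brought them to -0.24 and 0.17. The NK-like cells of the DR library also carried more transcripts of other lineages, with Igkc at 15.1 and 441.5 CPM, Jchain at 1.30 and 54.5 CPM and Ighm at 99 and 290.1 CPM in control and DR. Of 4 measured T cell markers, Cd3g (0.56) and Cd3d (0.43) were at least 25% higher (median 0.13, percentile 97.8), and Il7r, Ltb and Cd27 are T cell transcripts too. A filter on marker genes of other lineages, which did not count Cd3d, Cd3g, Il7r, Ltb or Cd27, left out 5 control and 6 DR cells. Igkc was then at 13.4 and 31.9 CPM and Jchain at 0.912 and 1.24 CPM, and the medians of the mature and immature lists were -0.43 and 0.61. These medians do not settle how much T cell RNA entered. With the clusters of at least 50 cells weighted equally Itgam was at -0.27, Gzmb at -0.077, Cd27 at 0.23 and Ltb at 0.15, all between the limits, with Emb at 0.43, Il7r at 0.45, Ctla2a at 0.44, Zeb2 at -0.35 and Kit at -1.30.

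**Figure D1:**
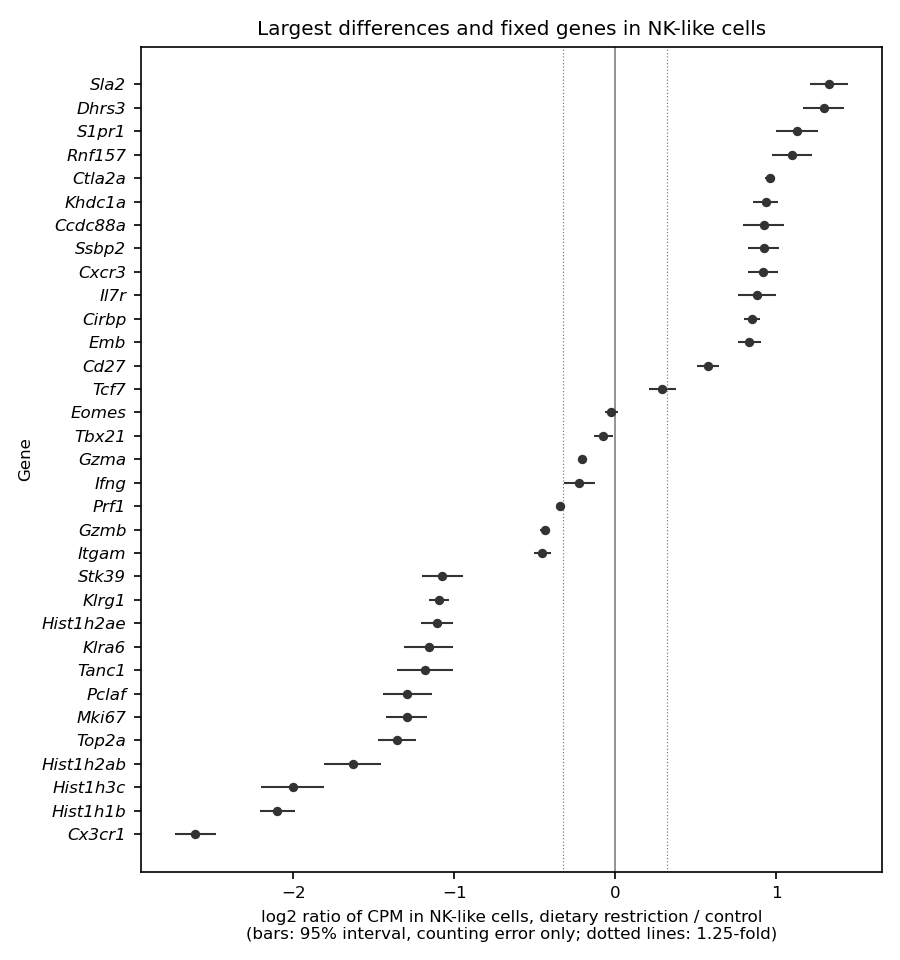
Log2 ratio of CPM in NK-like cells, dietary restriction over control (x axis), for the genes with the largest differences each way and the genes fixed in advance (y axis). Points are ratios from 1 library per group, bars are 95% intervals for counting error only, and dotted lines mark levels 25% higher and 20% lower; Cx3cr1 lies at -2.61, Eomes at -0.025 and Sla2 at 1.33.

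Among all 5847 genes with a mean of at least 20 CPM in NK-like cells, 3.08% were at least 25% higher and 7.95% at least 20% lower in the DR library, counted by ratio alone. That split depended on the scaling, with 5.30% higher and 4.43% lower under median-of-ratios scaling, and 5.05% and 4.72% when ribosomal and mitochondrial genes were left out of the total. With immunoglobulin, T cell receptor, mitochondrial and ribosomal genes and markers of other cell types left out of the ranking (Igkc and Jchain, at log2 ratios of 4.87 and 5.39, lay above it), the highest-ranked gene in the DR library was Sla2 (ENSMUSG00000027636, chromosome 2, 156872457 to 156887192), which encodes an adaptor that dampens antigen receptor signalling, at 23.7 CPM in control and 59.5 CPM in DR cells (log2 ratio 1.33, 1.21 to 1.45). Dhrs3, a retinaldehyde reductase gene, followed with a log2 ratio of 1.29 (1.17 to 1.42), then S1pr1 with 1.13, and Rnf157, which encodes a ubiquitin ligase, with 1.1 (0.97 to 1.22). Cirbp, which encodes a cold-inducible RNA-binding protein, was at 159 CPM in control and 286 CPM in DR cells (log2 ratio 0.85, 0.80 to 0.90). The 12 ranked highest also held Ctla2a (0.96), Khdc1a (0.93), Ssbp2 (0.92), Ccdc88a (0.92), Cxcr3 (0.92), Il7r (0.88) and Emb (0.83). On the lower side, Tanc1 had a log2 ratio of -1.18, Klra6 of the Ly49 receptor family -1.16, and the kinase gene Stk39 -1.07. Reads of Klra6, of the other Klra genes, of Ctla2a, Khdc1a, Bcl2a1b and the histone genes may be split or shared with near-identical paralogs, so their values are uncertain. With the 9 clusters weighted equally the ratios of Sla2, Khdc1a, Ssbp2 and Ctla2a were 0.87, 0.45, 0.52 and 0.51.

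Receptors that direct NK cell traffic differed in both directions. S1pr1, the sphingosine-1-phosphate receptor that guides lymphocyte exit from tissue, was at 21.9 CPM in control and 47.8 CPM in DR cells (log2 ratio 1.13, 1.0 to 1.26), and it was at 0.54 with the clusters weighted equally. The chemokine receptor Cxcr3, which responds to interferon-induced chemokines, had a log2 ratio of 0.92, and Cxcr4, the receptor for Cxcl12, 0.83. Of the 15 measured homing and adhesion genes, 4 were at least 25% higher, 4 were lower (Cx3cr1 and S1pr5 among them) and 7 were between the limits. The median of the homing list was -0.18, at percentile 1.30 of the random lists. It was -0.12 with median-of-ratios scaling and -0.11 with members from 5 CPM counted. Cx3cr1 (ENSMUSG00000052336) lies on chromosome 9 between 119901616 and 120069879, and S1pr1 (ENSMUSG00000045092) on chromosome 3 between 115710433 and 115715072.

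Cell cycle transcripts were lower in the DR library. Mki67, a marker of cycling cells, was at 58.0 CPM in control and 23.6 CPM in DR cells (log2 ratio -1.30, -1.42 to -1.17). Top2a, the topoisomerase of dividing cells, had a log2 ratio of -1.35, Pclaf, a factor bound to the replication clamp, -1.29, and Stmn1 (stathmin) -0.89. Of the 9 measured cell cycle genes, 6 were at least 20% lower and 3 between the limits, with a median of -0.41 at percentile 0 of the random lists. With members from 5 CPM counted the median was -0.97. The histone genes Hist1h1b, Hist1h3c, Hist1h2ab and Hist1h2ae had ratios of -2.10, -2.00, -1.63 and -1.11. With all clusters weighted equally, however, Hist1h1b turned to 0.018 and Hist1h2ab to 0.46, and Hist1h3c was at -0.51. Much of the difference in the median lay in 1 cluster of proliferating cells, named from the cell cycle list itself, so no order of its shares is read. It held 96 control cells (2.07% of NK-like cells, 1.68 to 2.52) and 33 DR cells (0.736%, 0.507 to 1.03). Without that cluster the median of the list was -0.16, Top2a was at -0.41, Pclaf at -0.40, Stmn1 at -0.28, Hist1h2ab at -0.23, Hist1h1b at -0.49 and Hist1h2ae at 0.018. Mki67 and Hist1h3c stayed lower, at -1.54 and -1.46. With NK-like cells rich in transcripts of other lineages left out (5 control and 6 DR cells), Mki67 was at -1.98, and with NK cells picked by single-cell gating it was at -3.02.

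Of the cytotoxic effector genes, Gzmb and Prf1 were at least 20% lower in the DR library and the other 8 measured genes were between the limits. Prf1 was at 1207 CPM in control and 953 CPM in DR cells (log2 ratio -0.34, -0.36 to -0.32), and Gzma (granzyme A) at 13685 and 11868 CPM (log2 ratio -0.21). The median of the effector list was -0.054, at percentile 44.0. With the 7 clusters of at least 50 cells weighted equally, Gzmb was at -0.077 and Prf1 at -0.18. Among 8 cytokine and chemokine genes (median -0.10, percentile 34.5), Ccl3 and Ccl4, which encode macrophage inflammatory proteins, were lower, with log2 ratios of -0.91 and -0.49, Ltb was higher, and Ifng (interferon gamma) was at -0.22, between the limits. With all clusters, the clusters of at least 50 cells, or the clusters after centring weighted equally, Ifng was at -0.61, -0.41 and -0.72, past the lower limit. With NK cells picked by single-cell gating, Ccl3 was at -0.60 and Ccl4 at -0.32, and with the clusters of at least 50 cells weighted equally Ccl4 was at -0.20, between the limits.

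Of 14 activating receptor and adaptor genes, 3 were lower, 1 was higher and 10 were between the limits (median -0.032, percentile 57.7). Klra8 (Ly49H) was at 838 CPM in control and 507 CPM in DR cells (log2 ratio -0.73), Slamf7, a signalling receptor, at -0.69 and Cd247, the zeta chain adaptor, at -0.39, while Cd226 (DNAM-1) was at 0.37. Of 10 inhibitory receptor genes, Klrg1 and Klra7 (log2 ratio -0.34, and -0.28 with median-of-ratios scaling) were lower, and Klrb1b, which encodes an inhibitory receptor for a C-type lectin ligand, was higher at 0.70 (median of the list -0.16, percentile 6.05). That median was -0.096 with all clusters and -0.014 with clusters of at least 50 cells weighted equally. Of 17 transcription factor genes of NK development, Zeb2, Tox (-0.38) and Irf8 (-0.33) were lower, Lef1 (0.37) was higher and 13 were between the limits, with Tcf7 at 0.29 (median -0.074, percentile 41.1). With the clusters of at least 50 cells weighted equally Tcf7 turned to -0.17 and Irf8 was at -0.083, and with median-of-ratios scaling Tox was at -0.316 and Irf8 at -0.26, all between the limits. Tcf7 was past the upper limit with median-of-ratios scaling (0.36), single-cell gating (0.35) and the clusters after centring weighted equally (0.42).

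Among type I interferon response genes, Isg15, an interferon-induced ubiquitin-like protein, had a log2 ratio of -0.63, and Irf9, an interferon regulatory factor, had -0.61. Most of the 8 measured members of the list were between the limits and none was higher (median -0.27, percentile 0.43). Isg15 was at -0.043 within immature-like and -0.16 within mature-like NK cells, both between the limits, and Irf9 at -0.57 and -0.67. Glucocorticoid response transcripts went both ways with a positive median. Tsc22d3 (GILZ), a glucocorticoid-induced gene, was at 154 CPM in control and 238 CPM in DR cells (log2 ratio 0.63), whereas the kinase gene Sgk1, also glucocorticoid-induced, was at -1.03. Of the 8 measured glucocorticoid response genes, 4 were higher, including Il7r and Cxcr4, and 2, Sgk1 and the glucocorticoid receptor gene Nr3c1, were lower (median 0.32, percentile 100). Among 11 FOXO target genes (median 0.048, percentile 89.5), S1pr1, Il7r and Pik3ip1, an inhibitor of phosphoinositide 3-kinase (log2 ratio 0.80), were higher and 8 were between the limits. Of 11 genes of the interleukin-15 and STAT5 pathway, Socs1, a feedback inhibitor of cytokine signalling, was higher at 0.74 (0.30, between the limits, with all clusters weighted equally) and 10 were between the limits (median 0.053, percentile 90.3). Among 10 apoptosis regulators (median -0.17, percentile 5.48), Bcl2a1b, a survival gene, was at -0.91 and the pro-death gene Bcl2l11 (Bim) at 0.40.

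Transcripts of the mitochondrial genome were higher in the DR library, and nuclear genes of energy metabolism differed little. Of 12 measured mitochondrially encoded genes, 8 were at least 25% higher and 4 between the limits (median 0.44, percentile 100), with mt-Co2, a subunit of cytochrome c oxidase, at 2507 CPM in control and 4225 CPM in DR cells (log2 ratio 0.75). All 26 nuclear-encoded oxidative phosphorylation genes were between the limits (median -0.056, percentile 67.2), as were the 12 fatty acid oxidation genes (median 0.048, percentile 97.7) and the 4 measured cholesterol synthesis genes (median 0.0032, percentile 62.1). The glycolysis genes Hk1 (hexokinase 1), Pfkp (phosphofructokinase) and Ldha (lactate dehydrogenase A) were lower, at -0.39, -0.38 and -0.33, and the other 10 measured were between the limits (median -0.027, percentile 82.3). Pfkp at -0.315 and Ldha at -0.27 were between the limits with median-of-ratios scaling, as was Hk1 at -0.24 with the clusters after centring weighted equally. Of 85 genes matched as ribosomal proteins, Rps18 (0.38) and Rpl12 (0.37) were higher (0.27 and 0.28, between the limits, with the clusters of at least 50 cells weighted equally) and 82 were between the limits (median 0.16, percentile 100); the 1 gene at least 20% lower, Rps6ka1 (-0.34, and -0.27, between the limits, with median-of-ratios scaling), encodes a kinase that the name rule also took in. Slc3a2, an amino acid transporter subunit, was at 0.32, just past the limit (0.28, between the limits, with the clusters after centring weighted equally), among 6 genes of the ATF4 response (median -0.026, percentile 69.6), and Klf6 at 0.34 (0.24 with all clusters weighted equally) among 10 immediate early and stress genes (median 0.054, percentile 98.3), with the other members between the limits. All members were between the limits in the lists for autophagy and lysosome (12 genes, median -0.062, percentile 57.2), TGF-beta response (5 genes, median -0.045, percentile 65.5) and MHC class I presentation (11 genes, median -0.046, percentile 54.8). Of the medians in this paragraph below 0.1 in size, all but that of fatty acid oxidation changed sign under at least 1 alternative, and no direction is read from them.

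**Figure D2:**
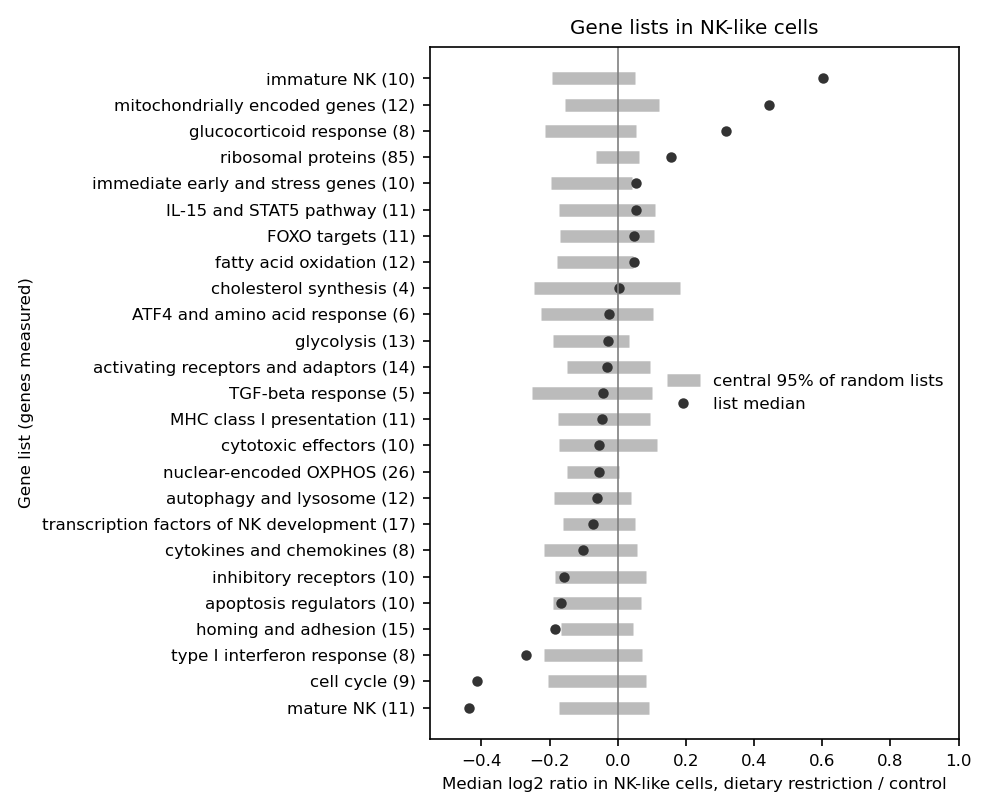
Median log2 ratio of each gene list in NK-like cells, dietary restriction over control (x axis; points), with the number of genes measured beside each list name (y axis). Grey bars span the central 95% of 10000 random lists of the same size matched on mean expression; the immature NK list lies above its bar at 0.60 and the mature NK list below its bar at -0.44.

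Shares of NK-like cells with at least 1 UMI of a gene were compared after thinning every cell to 3800 UMIs, which left out 326 control and 546 DR cells. A Cx3cr1 UMI was found in 24.8% of control cells (23.6 to 26.2) and 5.92% of DR cells (5.20 to 6.70), and a Klrg1 UMI in 44.6% and 24.6%. A Cd27 UMI was found in 22.3% of control and 32.0% of DR cells, a Cxcr3 UMI in 10.6% and 22.0%, and a S1pr1 UMI in 6.49% and 14.8%. An Eomes UMI was found in 65.2% of control cells (63.7 to 66.6) and 64.7% of DR cells (63.2 to 66.2). By Cd27 and Itgam together, the pair used to order NK cell maturation, 12.6% of control and 19.7% of DR cells had Cd27 only, 9.76% and 12.3% had both, 45.1% and 33.4% had Itgam only, and 32.5% and 34.6% had neither. Without thinning, at medians of 7085 UMIs in control and 5446 in DR NK-like cells, Cx3cr1 was found in 30.1% and 6.89%, Klrg1 in 54.9% and 30.8%, Cd27 in 36.5% and 42.1%, Itgam in 70.3% and 56.3%, Cxcr3 in 18.6% and 29.4%, S1pr1 in 11.6% and 20.2%, and Eomes in 80.5% and 76.5%. In B-like cells, which should lack most of these transcripts, the thinned shares in control and DR were 0.877% and 0% for Cx3cr1, 0.877% and 0.459% for Klrg1, 5.26% and 7.57% for Cd27, 1.75% and 0.688% for Itgam, 0% and 2.06% for Cxcr3, and 4.39% and 1.15% for Eomes, at median depths of 7785 and 6596 UMIs before thinning, with 40 and 44 cells left out. S1pr1 was found in 44.7% and 38.3% of B-like cells, which express this receptor themselves. Thinning NK-like cells to 4900 UMIs instead left out 577 control and 1697 DR cells, so the cells kept were a more selected part of the DR library. At that depth Cx3cr1 was found in 27.5% of control and 5.20% of DR cells, Klrg1 in 48.9% and 25.2%, and Itgam in 61.8% and 48.5%. Cd27 was found in 28.0% and 44.4%, and Eomes in 72.6% and 74.0%.

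**Figure D3:**
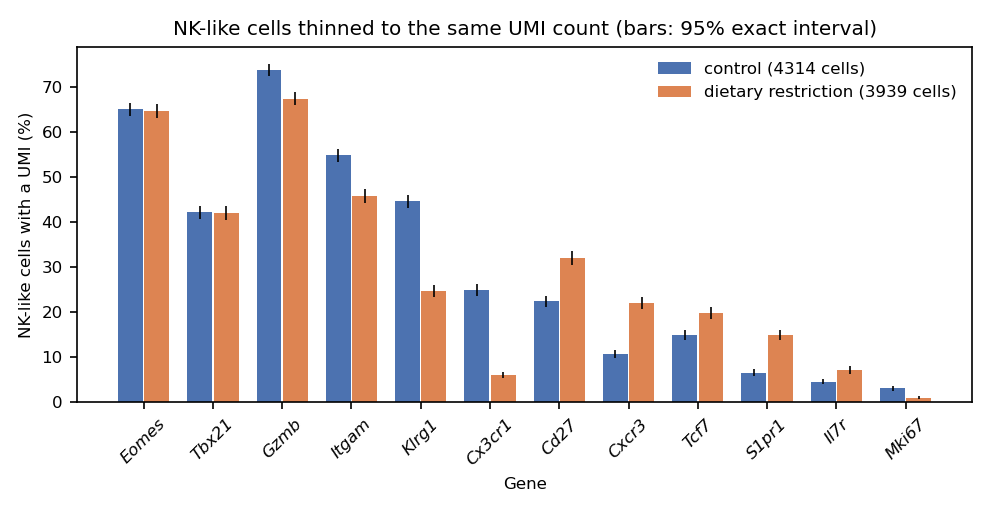
Percent of NK-like cells with at least 1 UMI of each gene (y axis, from 0) for 12 genes (x axis), after thinning every cell to 3800 UMIs, in 1 control and 1 dietary restriction library. Bars are shares and error bars are exact 95% binomial intervals; Eomes is at 65.2% and 64.7%, Cx3cr1 at 24.8% and 5.92%.

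NK-like cells were also divided into stages by clustering. Mature-like clusters held 60.6% of control NK-like cells (59.2 to 62.0) and 57.2% of DR NK-like cells (55.8 to 58.7), and immature-like clusters held 26.1% (24.8 to 27.4) and 35.8% (34.4 to 37.2). The immature-like class included a cluster of 178 control and 236 DR cells led by Batf3 and by the T cell receptor complex genes Cd3d and Cd3g. The libraries filled different clusters: 2436 control and 492 DR cells lay in mature-like cluster 0, led by Cx3cr1 and Klrg1, and 377 control and 2075 DR cells in mature-like cluster 1, led by Ly6c2. Because the genes that separate these clusters differed between the libraries, no order of the stage shares is read from them. After centring each library the immature-like shares were 29.3% and 33.1%, and the mature-like shares 56.7% and 58.6%. With doublets kept the immature-like shares were 15.8% and 32.9%, and the mature-like shares 52.6% and 57.3%.

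Within both stages, taken as whole classes, the levels of several genes still differed between the libraries. Among mature-like cells Cx3cr1 was at 216 CPM in control and 41.7 CPM in DR cells (log2 ratio -2.38), and among immature-like cells at 16.2 CPM (194 UMIs) and 0.644 CPM (8 UMIs; log2 ratio -4.65). Klrg1 had a log2 ratio of -0.98 within mature-like and -0.94 within immature-like cells, and Zeb2 of -0.45 and -0.70. S1pr1 was at 1.53 within mature-like and 0.76 within immature-like cells, Sla2 at 1.39 and 1.26, and Cirbp at 0.87 in both. Eomes was at 324 CPM in control and 344 CPM in DR cells within the mature-like class (log2 ratio 0.083, but -0.030 in cluster 0 and -0.012 in cluster 1) and at 362 and 325 CPM within the immature-like class (log2 ratio -0.16). The median of the mature NK list was -0.35 within mature-like and -0.31 within immature-like cells, and that of the immature NK list was 0.38 in each. Control and DR cells of the mature-like class came mostly from clusters 0 and 1 respectively, and those of the immature-like class mostly from cluster 2 in both libraries. At resolution 1.2, however, immature-like cells also split by library. A cluster led by Kit held 503 control and 87 DR cells, and 1 led by Socs2 and Emb held 188 and 689. The ratios within the immature-like class may therefore also reflect a different mix of cells. Inside mature-like clusters 0 and 1 the differences were smaller, with Klrg1 at -0.44 and -0.41, Cx3cr1 at -1.19 and -1.54, and the median of the mature NK list at -0.0078 (-0.066 to 0.013) and -0.13 (-0.15 to -0.014).

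**Figure D4:**
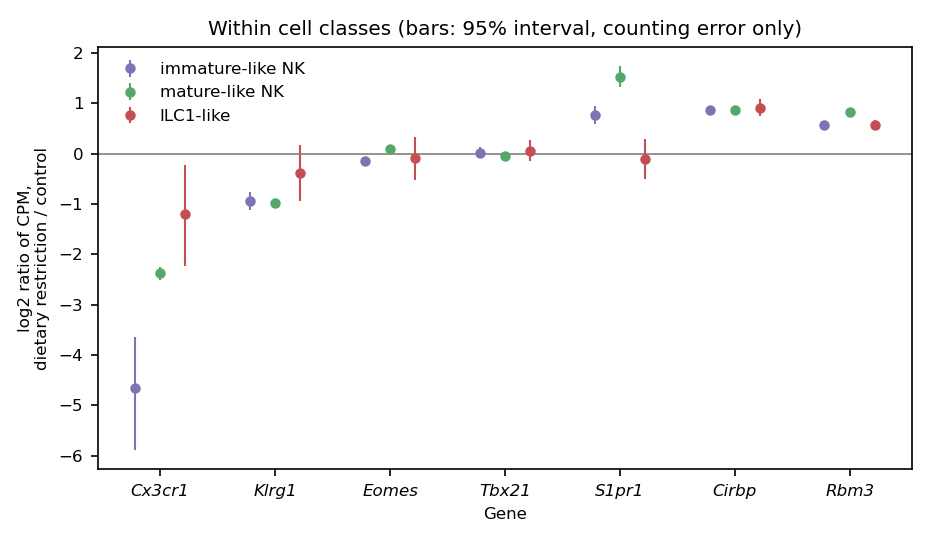
Log2 ratio of CPM, dietary restriction over control (y axis), for 7 genes (x axis) within immature-like NK, mature-like NK and ILC1-like cells. Points are ratios from 1 library per group and bars are 95% intervals for counting error only; Cx3cr1 lies at -4.65, -2.38 and -1.20, and Cirbp at 0.87, 0.87 and 0.91.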

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

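Each of these genes was at least 25% higher or at least 20% lower in the DR library, in the opposite direction in another cell class than in NK-like cells; the difference between the classes was not tested, and no explanation was weighed. Ccl3, which was lower in NK-like cells of the DR library, was higher in ILC1-like cells, with a log2 ratio of 0.39 (123 CPM in control and 161 CPM in DR cells). S1pr1, which was higher in NK-like cells, had a log2 ratio of -0.43 in B-like cells (209.6 and 155 CPM). Emb, also higher in NK-like cells, was at -2.15 in B-like cells, from 53 UMIs in control and 34 UMIs in DR cells. Stmn1, lower in NK-like cells, was at 1.82 in B-like cells (24 and 241 UMIs), and Irf8, a transcription factor of B and myeloid cells, was at 0.32 in B-like cells (255 and 319 CPM).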

How the results depend on the processing

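Among these settings, leaving out other-lineage, proliferating or low-RNA cells and weighting only clusters of at least 50 cells, or clusters made after centring, was chosen after the data were seen. Of the 66 named genes at least 25% higher or 20% lower in the DR library, 63 kept their sign and 44 stayed past these limits in all 13 settings. The cause was not tested unless stated. No paired analysis was possible because each group had 1 library.

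The NK-like share was 90.9% in control and 79.8% in DR cells with the stricter filter, 83.0% and 73.3% with no filter, 85.0% and 73.3% with single-cell gating, and 87.3% in control at resolution 1.2. The immature-like share was 27.6% and 39.6% with the stricter filter, 15.8% and 32.9% with doublets kept, and 29.3% and 33.1% after centring. The mature-like share was 63.3% and 55.4% with the stricter filter, 52.6% and 57.3% with doublets kept, and 56.7% and 58.6% after centring, so the order of the libraries turned in the last 2. With doublets kept, 29.5% of control and 9.10% of DR NK-like cells lay in unnamed clusters, against 11.2% and 6.24% in the main setting.

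The Eomes log2 ratio was 0.039 with median-of-ratios scaling, 0.033 without ribosomal and mitochondrial genes in the total, -0.24 with clusters weighted equally, -0.089 with clusters of at least 50 cells and -0.28 with clusters after centring. In the same order the immature NK median was 0.67, 0.66, 0.33 and 0.17 (not moved after centring) and the mature NK median -0.37, -0.38, -0.28 and -0.24. The immature median was 0.53 with single-cell gating, and the mature median -0.46 without proliferating cells. The cell cycle median was -0.55 with gating, -0.57 with gating and no filter, -0.16 without proliferating cells, -0.32 with cells weighted equally, -0.32 after centring and -0.97 when members from 5 CPM were counted, since more cell cycle genes then entered. Counted by ratio alone, whatever the interval, genes past these limits made up 45.6% with no expression limit, where low counts enter, and 1.81% at a ratio of 1.5.

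The 9 changes of sign counted as reversals came mostly from equal weighting of clusters. Other values near 0 also changed sign, some through scaling alone. With median-of-ratios scaling the ATF4 list turned from -0.026 to 0.039 and the glycolysis list from -0.027 to 0.037, and Eomes turned too. Hist1h1b was at 0.018 with all clusters and 0.039 with those of at least 50 cells. Hist1h2ab was at 0.46, 0.31 and, after centring, 0.34, and Hist1h2ae at 0.018 without the proliferating cluster, among whose top genes it lay. The immediate early list was at -0.055, -0.012 and, after centring, -0.025. Of the other values, 464 moved beyond their counting interval, 435 of them with the sign kept, and 1319 did not. The expression limit of 20 CPM left 9 of 18 cell cycle genes and 4 of 16 cholesterol synthesis genes.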

Other observations

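The tests of depth and within mature-like cells and clusters in the first pattern and of the handling response in the second were chosen after the results they measure had been seen. ILC1-like cells, a tissue-resident lymphocyte class that shares NK receptors, showed part of the NK-like differences. Sla2 had a log2 ratio of 1.07 in ILC1-like cells and Rnf157 1.03, close to their values in NK-like cells, and Pik3ip1 was at 1.1. Dhrs3 was at 1.0, Tsc22d3 at 0.64 and mt-Co2 at 0.80. Klra8 was at -1.45 and Zeb2 at -0.72. S1pr1 was at -0.11 and Cxcr3 at -0.051 in ILC1-like cells, both between the size limits, and Ltb was at -0.20. Irf9 was at -0.61 in ILC1-like and -0.91 in B-like cells, and Isg15 at -1.02 and -1.53; the interferon list as a whole was not measured in these classes.

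The mature NK list was lower in the DR library (median log2 ratio -0.44). Among cells of at least 3800 UMIs, lower depth per cell does not account for it alone. At equal depth 10 of the 11 list genes, all but Ly6c2, were still found in a smaller share of these DR cells (median log2 ratio of the shares -0.15, -0.23 to -0.13). Thinning left out 326 control and 546 DR cells of lower depth, so the mix of stages among the cells kept may differ from that of all cells. With cells rich in transcripts of other lineages left out, the median was -0.43 (-0.45 to -0.40). That filter removed only 5 control and 6 DR cells and did not count Cd3d, Cd3g or Trac, so it cannot exclude other cell types. Single-cell gating, which left out cells with a UMI of any of 6 T, B and myeloid genes, gave -0.45. Cells with such a UMI therefore do not account for the difference alone. Fewer mature cells and a lower level of maturation transcripts per mature cell cannot be told apart: the median was -0.35 (-0.39 to -0.32) within mature-like cells as a whole, but -0.0078 (-0.066 to 0.013) and -0.13 (-0.15 to -0.014) inside mature-like clusters 0 and 1, which were themselves separated by such genes. Both stay open, as does any other difference between the samples.

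Cirbp and Rbm3, whose transcripts rise at lower temperature, had log2 ratios of 0.85 and 0.63 in NK-like cells, 0.91 and 0.57 in ILC1-like cells and 0.72 and 0.68 in B-like cells. Their mean ratio was 0.79 (0.72 to 0.86) among NK-like cells with 2 to 3% mitochondrial UMIs (1068 control and 2130 DR cells). This cannot decide on damaged cells, because the median mitochondrial share of all NK-like cells was 1.59% in control and 2.43% in DR. The window thus held unlike parts of the libraries. A change of NK stage was argued against, because the mean ratio was at least 0.72 (0.65 to 0.78) within immature-like and within mature-like cells. Those classes were mixed differently in each library, but inside mature-like clusters 0 and 1 Cirbp was at 0.86 and 0.71 and Rbm3 at 0.77 and 0.62. In the proliferating cluster (96 and 33 cells) Cirbp was at -0.085 and Rbm3 at 0.40. Igkc was among the top genes of that cluster, so RNA of other lineages may enter its values. A lower temperature of the DR cells may be a candidate explanation: 17 measured of 18 listed heat shock chaperones, fixed before their values were seen, had a median of -0.20 (-0.24 to -0.18; percentile 0.53), with 4 of them at least 20% lower (Stip1 -0.58, St13 -0.57, Fkbp4 -0.48, Hspa4 -0.35) and 13 between the limits. The median of all described genes was -0.064, and the chaperones are not given under other scalings, within stages or without the proliferating cluster. A weaker handling response, set to need a median below -0.1, was not seen in 8 immediate early and stress genes (0.11, 0.066 to 0.16, percentile 99.4). That test was set after the median of the whole list, 0.054, was known, so it cannot decide the question. The list with its heat shock members turned to between -0.055 and -0.012 with clusters weighted equally. The chaperones were below -0.1 in ILC1-like cells (-0.21, -0.28 to -0.15), but the interval in B-like cells (-0.22, -0.27 to -0.069) reached past that limit, so a cause shared by all 3 classes stays open, and body temperature under restricted feeding and temperature during handling of the sample cannot be told apart with 1 library per group.

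Cell cycle transcripts were lower in the DR library (median log2 ratio -0.41). The median was -0.44 (-0.58 to -0.35) without the 5 control and 6 DR cells rich in transcripts of other lineages. With single-cell gating it was -0.55. That gate drops a cell with any UMI of the 6 genes, so it may also drop NK cells of high depth. The cycling cluster among all cells had a median of 18647 UMIs, against 7085 in control and 5446 in DR NK-like cells. The gated value therefore cannot decide the question. Cells of other types with less such RNA are not excluded, but the 5 control and 6 DR cells left out do not account for the difference. Removal of cycling cells as doublets does not either, with a median of -0.42 (-0.54 to -0.34) when doublet calls were kept. Fewer cycling NK cells under dietary restriction stays open as an untested biological explanation. Without the proliferating cluster (96 control and 33 DR cells) the median was -0.16, with Mki67 at -1.54.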
